A study of Mus musculus with 2 samples.

How the data were processed

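Glomeruli were isolated from mouse kidneys by graded sieving, per the labels' protocols, and total RNA was extracted and converted to biotinylated cRNA with a 3′ in vitro transcription kit for 1-colour Affymetrix arrays. The deposited values were 1 intensity per probe set and array on a linear scale, made with MAS5 per the submitters' processing notes, with the version not given in the sources used here. MAS5 compares perfect-match with mismatch probes of each probe set and scales each array to a common mean. From the values, the mean intensity after leaving out the lowest and highest 2% of the 45101 probe sets was 500.0 on both arrays, and no intensity was at or below 0. MAS5 detection calls were not used here. There were 2 arrays, 1 per genotype, and the groups were taken from the genotype in the labels, where +/+ was read as the absence of the Cre allele. The number of arrays limits the precision, and no p-value, standard error or test between animals can be had. Because each array was scaled to one mean, a difference says how a transcript stood relative to the rest of that sample, and a sample with less of one cell type reads higher for genes of the others.

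Values were used as deposited, without rescaling. The 64 control probe sets were left out of the gene table. Probe sets were named from GEO's platform annotation, with gene identifiers matched to the RefSeq gene table of GRCm38.p6, which was used only for names. Of 45037 other probe sets, 34945 had 1 gene symbol, 932 had several genes and 9160 had none listed. The identifiers of 34741 probe sets matched the RefSeq table, and 0 symbols needed updating. Genes were represented by the probe set with the highest mean log2 signal among those with 1 symbol, without cross-hybridising sets (suffix _x_at) where another existed. This gave 18193 genes. The floor was the mean over the arrays of the 40th percentile of the signals, 52.7, and lower signals were raised to it before log2. A gene was measured where its higher signal reached the floor (13290 genes), and 12284 reached it in both arrays. Folds against a signal below the floor were computed against the floor and are given as lower bounds. Of the probe sets without exactly 1 gene, 4065 were measured, of which 78 were at least 2-fold higher and 71 at least 2-fold lower. These have no part in the gene counts.

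Genes were counted where they differed at least 2-fold. To place a single gene, its percentile and a robust SD were taken among genes of like mean signal. The 37 gene lists and the rules for counting, ranking and naming were fixed before the data were examined; what was chosen later is stated where it is used. Of 831 distinct listed genes, 741 had a named probe set and 694 were measured; the others are not analysed here. A list was summarised by the median log2 difference of its measured members and the percentile of that median among 10000 random lists of the same size, matched on mean signal in 20 bins. It was said to stand apart below percentile 2.5 or above 97.5, and percentiles are given rounded. The percentiles describe these arrays only. Intervals of differences between list medians came from 10000 bootstrap draws of genes, which are not replicates. Some genes are on more than 1 list. The lists of the deleted genes and of sex-linked genes were given as values only.

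The genes named in the text followed a rule. It took every probe set of the deleted genes, the 12 highest and 12 lowest genes at or above the floor in both arrays whose other probe sets differed in the same direction, the 4 genes per direction with the brightest signal whose other array was below the floor, and up to 4 members of each list with the largest difference in size. Predicted and unnamed symbols were left out. Genes outside the rule are marked as such where they are named.

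RNA quality was read from the control probe sets. The 3′ over 5′ signal ratio was 1.29 in the double knockout and 1.36 in the control for Actb, and 0.697 and 0.706 for Gapdh. The trp control had a mean signal of 5.30 and 5.76, below the floor. The bioB, bioC and bioD hybridisation controls differed by -0.19, -0.07 and -0.17 on the log2 scale. The cre control on these arrays is an added bacteriophage transcript and does not measure the transgene.

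Alternatives comprised other floors (the 25th and 60th percentiles, none, and a pseudocount of 32 in place of the floor), other scalings (median and 75th percentile centring, quantile normalization, removal of a loess trend on signal), other choices of probe set, other size rules (1.5-fold and 3-fold), and for the lists the mean in place of the median, unmatched random lists, and members left out. Recentring on the median of the podocyte, endothelial, mesangial and parietal markers was added after the data were examined. The steps were tested on simulated signals of 12870 genes with 200 changed by known amounts. The share past the 2-fold rule was 10% of genes changed 1.5-fold, 34% of those changed 2-fold, 98% at 4-fold and 100% at 8-fold, and 2.82% of unchanged genes were past it. A simulated list shifted by 0.5 was recovered with a median of 0.66 at percentile 100, and 3.25% of 400 unshifted lists fell outside the limits. The simulated noise took the robust SD of the real differences between the arrays and was drawn independently for each gene. That spread includes any real difference between the samples, so 2.82% is not a rate of false calls in these arrays. The 3.25% does not cover lists whose members move together. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.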

Results

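Glomerular gene expression was measured in male C57BL/6J mice that carried floxed alleles of GC-A and p38. GC-A is the guanylyl cyclase receptor for the natriuretic peptides, and p38 is a stress-activated kinase. One array held RNA from mice with the nephrin promoter driving Cre, which deletes floxed sequence in podocytes, the epithelial cells of the glomerular filter (the double knockout). The other array held RNA from floxed mice without Cre (the floxed control). At 2 months of age both genotypes had received a diet with 6% NaCl and aldosterone at 0.2 µg per kg of body weight per minute from an implanted minipump for 3 weeks, a load of salt and mineralocorticoid hormone. The comparison asked how glomerular transcripts differed between the genotypes under this load. Each genotype had 1 array, and the labels do not say how many mice gave the RNA of an array. No difference given here therefore has a replicate check, and the words higher and lower describe these arrays, as the double knockout against the floxed control. The median signal over all probe sets was 94.7 in the double knockout and 88.6 in the control, and the floor below which a signal was taken as not measured was 52.7.

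The targeted genes were read first. Npr1, which encodes GC-A, had a signal of 102 in the double knockout and 167 in the control, a log2 difference of -0.71 or 1.63-fold lower. This placed it at percentile 7.68 of genes of like signal, whose log2 differences had a robust SD of 0.58. Mapk14, which encodes p38α, is taken here as the floxed p38 gene, since the labels name no isoform. Its brightest probe set read 2607 in the double knockout and 2628 in the control, a log2 difference of -0.01. Among the other Mapk14 probe sets above the floor the differences ran from -0.23 to 0.25. Recentring all differences on glomerular cell markers, a setting chosen after seeing the data, put Npr1 at -1.27 and Mapk14 at -0.58. It subtracts the same 0.57 from every gene. The medians of cytosolic ribosomal protein genes and of housekeeping genes became -0.64 and -0.68 by it. The shift alone therefore says nothing about deletion. Podocytes are one of several cell types in a glomerulus, and the positions of these probe sets relative to the floxed exons are not given in the sources used here. A probe set outside the deleted part checks nothing, so the Mapk14 values neither bear out nor contradict the labels.

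Among 13290 measured genes, 469 (3.53%) were at least 2-fold higher in the double knockout and 382 (2.87%) at least 2-fold lower. A 4-fold difference was reached by 35 genes upward and 9 downward. Of the genes past 2-fold, 55.1% were higher. That share was 47.4% with the floor at the 60th percentile (274 higher, 304 lower) and also depended on the scaling of the arrays, at 38.6% after centring on the median or the 75th percentile (333 higher, 530 lower), 45.0% after quantile normalization and 3.63% after recentring on glomerular cell markers. Where a gene past 2-fold had a second probe set above the floor, that probe set differed in the same direction for 151 of 163 higher genes and 106 of 110 lower genes, against 4076 of 5418 (75.2%) over all genes with a second probe set. It was itself past 2-fold for 79 and 61 of them.

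The highest gene was Inhbb, the βB subunit of inhibins and activins, with a signal of 1457 in the double knockout and 90.1 in the control (16.2-fold). The gene for the adhesion molecule Vcam1 was 7.08-fold higher (3241 against 458), and Havcr1, which encodes kidney injury molecule 1, was 6.36-fold higher (2272 against 357). Cd44, a hyaluronan receptor, was 5.50-fold higher, and the stress-response gene Gadd45b was 4.72-fold higher. The matrix genes Col5a3, Mmp2 and Fn1, which encode a collagen V chain, gelatinase A and fibronectin, were 5.31-fold, 5.21-fold and 4.57-fold higher. Nell2 (9.41-fold), Nkain4 (8.38-fold), Igfbp2 (6.40-fold) and the cadherin gene Cdh6 (5.47-fold) completed the 12 highest. Second probe sets gave smaller log2 differences for several of these genes, at 1.42 for Inhbb (4.01 in the probe set above), 1.38 and 2.10 for Vcam1 (2.82), 1.87 for Havcr1 (2.67) and 1.70 for Mmp2 (2.38). A further 59 of the higher genes had a control signal below the floor, so their folds are lower bounds. The brightest of these was Ccl2, which encodes a monocyte chemoattractant, at least 10.5-fold higher. Gdpd2 was at least 8.47-fold, and the epidermal genes Crct1 and Cdsn were at least 5.56-fold and 4.92-fold higher.

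The lowest gene was Bhmt, which encodes an enzyme that remethylates homocysteine, with a signal of 69.8 in the double knockout and 658 in the control (9.43-fold lower). Hpd, which encodes an enzyme of tyrosine breakdown, was 8.48-fold lower. Afmid (kynurenine formamidase) and Gnmt (glycine N-methyltransferase) were 5.29-fold and 4.54-fold lower, and the cytochrome P450 genes Cyp2d12 and Cyp2d9 were 6.91-fold and 3.84-fold lower. Idi1, an enzyme of isoprenoid synthesis, and Insig1, a regulator of sterol synthesis, were 3.76-fold and 3.75-fold lower. The remaining genes of the 12 lowest were Igfbp1 (4.75-fold), Azgp1 (3.87-fold), A1cf (3.80-fold) and Apom (3.73-fold). Other probe sets read -1.24 and -1.22 for Afmid (-2.40 in the probe set above) and -1.25 for Idi1 (-1.91). In 21 lower genes the double knockout signal was below the floor. Mfsd2a, a carrier of lysophospholipids, was at least 4.35-fold lower, Crabp1 at least 3.53-fold, Mapk8ip2 at least 3.23-fold and Ambp at least 2.67-fold.

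**Figure D1:**
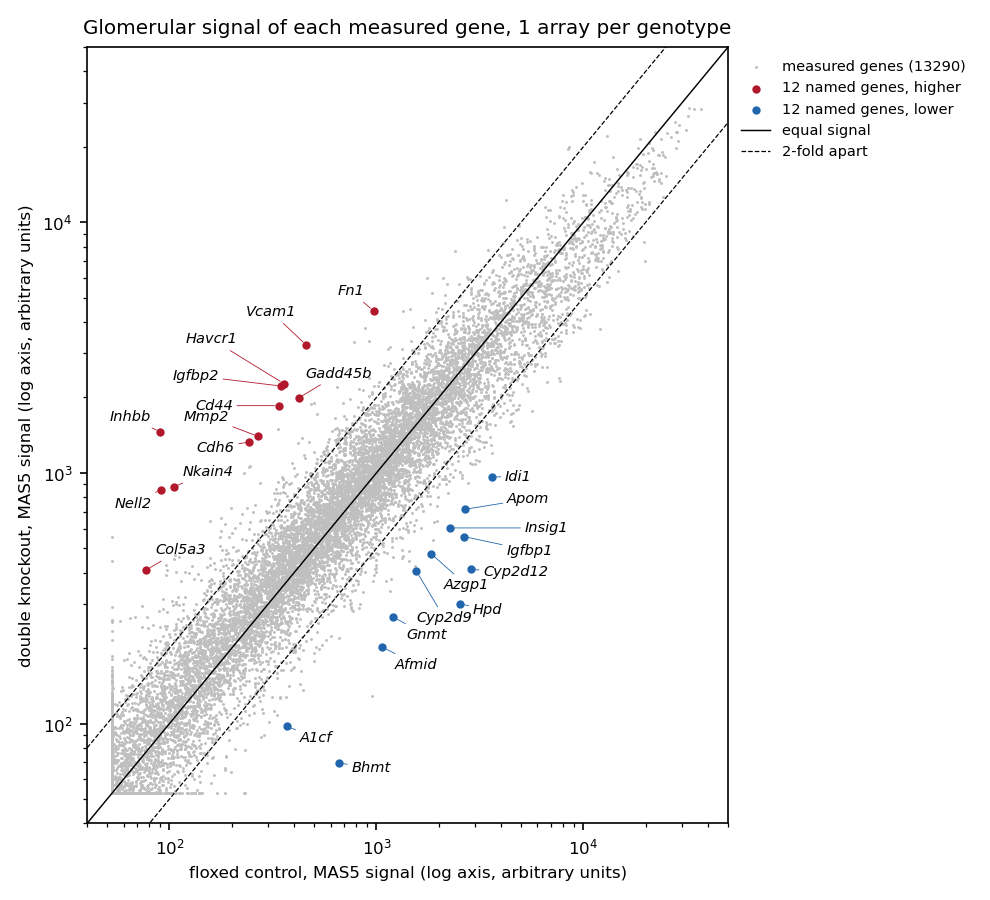
Each grey point is a measured gene, with its MAS5 signal in the floxed control on the horizontal axis and in the double knockout on the vertical axis (arbitrary units, both axes logarithmic, signals below the floor drawn at the floor). The 12 highest genes (red) run from Fn1 (4.57-fold) to Inhbb (16.2-fold) and the 12 lowest (blue) from Apom (3.73-fold) to Bhmt (9.43-fold), with the solid line at equal signal and the dashed lines 2-fold away.

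Marker lists of the cell types of the kidney separated the arrays in opposite directions. Markers of the proximal tubule, the segment that reabsorbs most of the filtrate, had a median log2 difference of -0.79, with all 28 measured members below 0 and 3 of them at least 2-fold lower. These were Dpys (3.17-fold), Slc7a13 (2.70-fold) and the organic anion transporter gene Slc22a8 (2.21-fold). Markers of the loop of Henle, distal tubule and collecting duct had a median of -0.67, with all 23 below 0 and Slc4a1 (2.99-fold) and Calb1 (2.37-fold) at least 2-fold lower. Glomerular endothelial markers had a median of 0.72, or 0.15 after recentring on glomerular markers, with all 27 above 0 before it. Gpihbp1 (2.73-fold), Cd34 (2.22-fold) and Fabp4 (2.22-fold) were at least 2-fold higher. Another Fabp4 probe set read -0.19. Mesangial and mural markers, from the contractile cells that support the capillaries, had a median of 0.63, or 0.06 after recentring on glomerular markers. Of these, 5 of 21 were at least 2-fold higher, among them Tagln (3.23-fold), Ptn (2.38-fold) and Des (2.20-fold, but -0.03 on the log2 scale in the Des probe set of median difference). Apart from cross-hybridising sets, no other Des probe set reached the floor in both arrays.

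Podocyte markers had a median of 0.47, which became -0.10 when all differences were recentred on glomerular markers. Of the 31 measured podocyte markers 1 was at least 2-fold higher, Kirrel (2.20-fold), and none at least 2-fold lower before recentring, with 24 above 0 and 7 below. Ptpro read 1.97-fold, Myo1e 1.94-fold and Plce1 1.82-fold higher. The lowest were Tdrd5 (1.81-fold lower) and Sema3g (1.66-fold lower), which fell outside the naming rule and were picked after their values were seen. The slit diaphragm and actin regulators of podocytes had a median of 0.52, or -0.04 after that recentring, with Inf2 (2.77-fold) and Kirrel at least 2-fold higher among 19. Parietal epithelial markers, of the cells that line Bowman's capsule, had a median of 0.52, or -0.04 after recentring, with Cd44 (5.50-fold), Ccn2 (2.32-fold), Cldn1 (2.18-fold) and Ncam1 (2.02-fold) at least 2-fold higher among 15. Over the 94 glomerular cell markers together the median was 0.57, which is 1.48-fold higher and serves as the reference for the lists that follow. Each of these lists lay outside the central 95% of its 10000 random lists of equal size matched on signal, with percentiles of 0.00 for both tubule lists and at least 99.95 for the others.

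**Figure D2:**
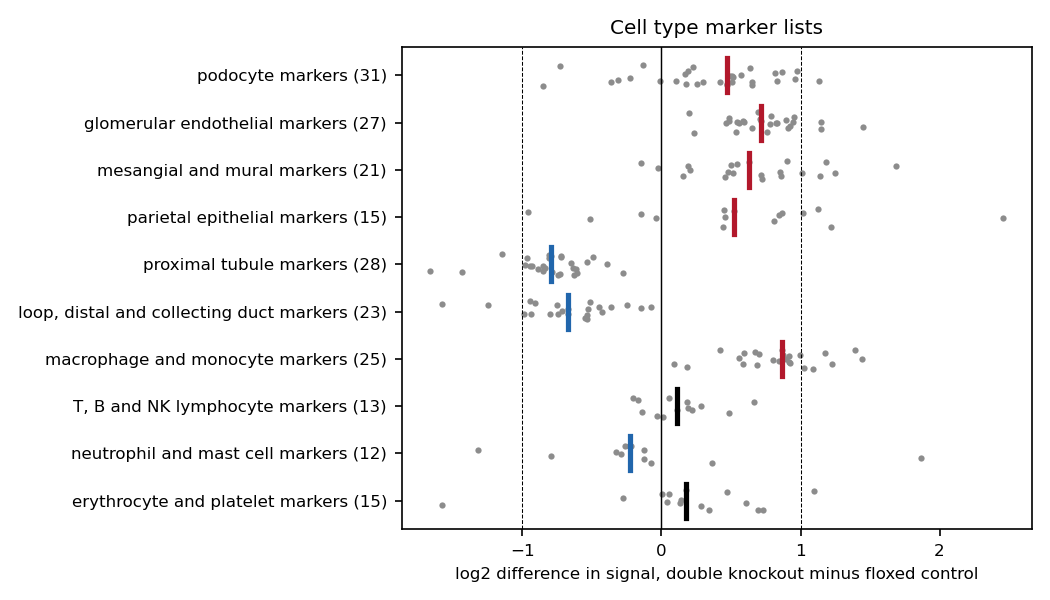
Each grey point is a measured marker gene, placed by its log2 difference in signal (double knockout minus floxed control, horizontal axis) within its cell type list (vertical axis, number of genes in parentheses). Thick bars are list medians (red above and blue below the random lists, black neither), the dashed lines mark 2-fold, and the tubule medians of -0.79 and -0.67 lie opposite the endothelial median of 0.72, with the podocyte (0.47) and parietal (0.52) medians becoming -0.10 and -0.04 if recentred on glomerular markers.

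Genes of kidney injury and of matrix had higher medians than the glomerular markers. Kidney injury markers had a median of 1.10, or 0.53 after recentring on glomerular markers, and 10 of 18 were at least 2-fold higher. Beside Vcam1, Havcr1 and Cd44 these included Lcn2, which encodes the secreted lipocalin NGAL (3.65-fold, 3359 against 920). Genes of extracellular matrix and fibrosis had a median of 0.77, or 0.20 after recentring, with 15 of 39 at least 2-fold higher and none at least 2-fold lower. The highest were Mmp2, Fn1, Tgfb2, which encodes a transforming growth factor β (4.31-fold), and the tenascin gene Tnc (3.41-fold). Both lists were at percentile 100 of their random lists, in arrays in which the tubule lists were lower.

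Macrophage and monocyte markers had a median of 0.87, or 0.30 after recentring on glomerular markers, with all 25 measured members above 0 and 6 at least 2-fold higher. C1qc was 2.72-fold higher, the chemokine receptor gene Ccr2 2.62-fold, C1qa 2.26-fold and Aif1, with a control signal below the floor, at least 2.34-fold. Genes of foam cells and lipid handling had a median of 0.70, or 0.14 after recentring, with 3 of 19 at least 2-fold higher, namely Gpnmb (4.44-fold), Fabp4 and the phagocytic receptor gene Mertk (2.14-fold), while Pltp read 1.99-fold. Both were at percentile 100. Markers of T, B and NK lymphocytes had a median of 0.11, at percentile 58.0, with none of 13 past 2-fold. The largest difference was that of Ptprcap (0.67). Of 21 such markers with a named probe set only these 13 were measured, and 3 of them had a signal below the floor. Ighm was the brightest, at 257 in the double knockout and 225 in the control, followed by Ms4a1 at 133 and 109. With signals this low, the list cannot show whether lymphocytes differed between the samples. Erythrocyte and platelet markers did not stand apart either, with a median of 0.17 at percentile 71.1; F13a1 was 2.14-fold higher and Slc4a1, also a collecting duct gene, 2.99-fold lower. Neutrophil and mast cell markers had a median of -0.23 at percentile 1.42, with Mmp9 at least 2.49-fold lower, S100a9 1.73-fold lower and Lcn2 higher. That list no longer stood apart when the mean replaced the median (-0.13, percentile 5.93).

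Chemokines, cytokines and inflammatory signalling genes had a median of 0.42, or -0.14 after recentring on glomerular markers, with 6 of 27 at least 2-fold higher. After Ccl2 the largest differences were those of the neutrophil chemoattractant genes Cxcl2 (4.05-fold) and Cxcl5 (at least 2.90-fold) and of Cxcl13 (2.85-fold), a chemoattractant of B cells. Complement genes had a median of 0.44, or -0.13 after recentring, with C1qc, Masp1 (2.52-fold) and C1qa at least 2-fold higher among 18. Interferon response genes had a median of 0.59, or 0.02 after recentring and 0.28 with the mean over probe sets, with H2-D1 (2.14-fold) and Gbp2 (2.00-fold) at least 2-fold higher among 25. Genes of MHC class II and antigen presentation had a median of 0.49, or -0.08 after recentring, with Cd74 (2.00-fold) past 2-fold among 10 and Ctss, also a macrophage marker, at 1.99-fold. All of these lists were above percentile 99.7.

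Genes of endothelial activation and adhesion had a median of 0.53 at percentile 100, or -0.03 after recentring on glomerular markers. Vcam1, Lrg1 (2.73-fold) and Edn1 (2.02-fold), which encodes endothelin 1, were at least 2-fold higher among 23, and Angpt1 (angiopoietin 1) was 1.85-fold lower. Genes of coagulation, fibrinolysis and thrombosis had a median of 0.46 at percentile 100, or -0.11 after recentring, but their members went both ways. F8 (2.73-fold), F13a1 and Thbs1 were at least 2-fold higher, and Serpinf2 (2.54-fold), Proc (2.25-fold) and Serpinc1 at least 2-fold lower, among 30. Thbs1 and Serpinc1 fell outside the naming rule and were picked after their values were seen. With the mean in place of the median this list did not stand apart (0.18, percentile 95.1).

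Genes of natriuretic peptide and cGMP signalling other than the deleted receptor had a median of 0.62 at percentile 100, or 0.05 after recentring on glomerular markers, with none of 13 past 2-fold. The largest differences were those of the cGMP phosphodiesterase gene Pde5a (1.85-fold, second probe set 0.16 on the log2 scale), the cGMP-dependent kinase genes Prkg2 (1.79-fold) and Prkg1 (1.75-fold), and Nppb, which encodes brain natriuretic peptide and had a control signal below the floor (at least 1.69-fold higher). Genes of the p38 family and its effectors had a median of 0.30 at percentile 96.0, or -0.26 after recentring on glomerular markers, and did not stand apart, although their mean of 0.34 did, at percentile 98.1. Their median was 0.12 with the mean over probe sets, 0.18 with the probe set of median difference and 0.20 after quantile normalization. Mapk11, which encodes p38β (2.55-fold), the phosphatase gene Dusp10 (2.37-fold) and the heat shock gene Hspb1 (2.26-fold) were at least 2-fold higher, and Mapk12, which encodes p38γ, read 1.55-fold. Mineralocorticoid and glucocorticoid targets had a median of 0.03 at percentile 58.0, or -0.06 after median centring, with Tsc22d3 (2.26-fold) and Edn1 at least 2-fold higher among 19, Pik3r1 at 1.93-fold higher and Ndrg2 at 1.98-fold lower. Genes of the renin-angiotensin system had a median of 0.15 and a mean of -0.02, at percentile 82.8 of the median, with none of 7 past 2-fold. Their largest differences were those of the peptidase genes Anpep (1.89-fold lower) and Mme (1.54-fold higher). Genes of oxidative stress and the NADPH oxidases had a median of -0.24 at percentile 10.1, with none of 22 past 2-fold, and a median of -0.15 after removal of the loess trend; Sod3 was 1.94-fold, Sod2 1.74-fold and Nqo1 1.69-fold lower, and Ncf4 1.87-fold higher. That list stood apart under random lists not matched on signal, at percentile 0.36, and with the mean over probe sets (-0.28, percentile 1.43).

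Lists of lipid and mitochondrial metabolism were lower. Cholesterol and sterol synthesis genes had a median of -1.07, below all of their random lists, with all 16 measured members below 0 and 9 at least 2-fold lower. Idi1 and Insig1 were followed by Msmo1 (2.74-fold) and Cyp51 (2.43-fold, other probe sets from -1.10 to -0.25 on the log2 scale). With the mean over probe sets the list median was -0.74, against -0.74 for the proximal tubule markers. Genes of mitochondrial oxidative phosphorylation had a median of -0.57 at percentile 0.14, or -0.36 after quantile normalization and -1.14 after recentring on glomerular markers, with all 29 below 0 and none at least 2-fold lower, led by Ndufs1 (1.75-fold), Uqcrfs1 (1.73-fold), Uqcrc2 (1.72-fold) and Sdhd (1.66-fold). Genes of fatty acid oxidation and the peroxisome had a median of -0.50 at percentile 0.10. Of 19, Cyp4a14 (2.24-fold), Ehhadh (2.19-fold) and Acaa1b (2.16-fold) were at least 2-fold lower, and Pdk4, which encodes an inhibitor of pyruvate oxidation, was 2.22-fold higher. Genes of hypoxia and glycolysis did not stand apart (median -0.07, mean 0.00, percentile 29.4), with Hk2 (2.90-fold) and Pfkfb3 (2.70-fold) at least 2-fold higher, Adm 1.87-fold higher and Car9 2.60-fold lower. The proximal tubule, whose markers had a median of -0.79 in these arrays, expresses many genes of these metabolic lists.

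Cell cycle genes had a median of 0.59 at percentile 100, or 0.03 after recentring on glomerular markers, with 4 of 27 at least 2-fold higher. These were the proliferation marker gene Mki67 (2.75-fold), Ube2c (2.75-fold), Top2a (2.33-fold) and Tpx2 (2.11-fold, with a second probe set at -0.17 on the log2 scale). With the floor at the 60th percentile the median was 0.28, at percentile 97.4. Immediate early and stress response genes had a median of 0.35 at percentile 99.9, or 0.21 with the probe set of median difference and -0.21 after recentring on glomerular markers, with Gadd45b, Myc (3.00-fold), Socs3 (2.38-fold) and Egr3 (2.14-fold) at least 2-fold higher among 31; the second Egr3 probe set read -0.70. Genes of apoptosis and survival had a median of 0.46 at percentile 100, or -0.11 after recentring. The cell cycle inhibitor gene Cdkn1a (2.21-fold) was at least 2-fold higher among 20, and Apaf1 read 1.91-fold, Birc3 1.61-fold (second probe set -0.10) and Bcl2l11 1.60-fold. Genes of the unfolded protein response had a median of 0.12 at percentile 91.7, or 0.02 after median centring and 0.06 with the probe set of median difference. None of 24 was past 2-fold, with Sel1l (1.43-fold), Ddit3 (1.41-fold), Edem1 (1.40-fold, second probe set -0.21) and Manf (1.35-fold) leading.

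Reference genes did not stand apart as groups. The 18 cytosolic ribosomal protein genes had a median of -0.08 at percentile 79.6, which became 0.12 after quantile normalization. Their differences ran from -0.28 (Rps2) to 0.18 (Rps24), with Rplp0 and Rpl27 both at -0.16 and at 0.13 and 0.10 after quantile normalization. Housekeeping genes had a median of -0.11 at percentile 49.7, with Tfrc 2.21-fold lower, Sdha 1.64-fold lower (another probe set read 0.21), Pgk1 1.56-fold lower and Tubb5 1.70-fold higher among 15. The Y-linked genes Kdm5d, Eif2s3y and Uty differed by -0.13, -0.06 and -0.05, and Xist, a transcript of female cells, was near or below the floor in both arrays (49.0 and 64.4), in arrays of male mice. Of the 35 lists ranked, 19 were higher, 6 lower and 10 neither. By chance 1.75 would fall outside if genes within a list varied independently, which genes of a cell type or pathway need not do. Of the 19 higher lists, 10 had medians below the glomerular marker median of 0.57. Recentring on that median also turned every positive median among the lists that did not stand apart negative.

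**Figure D3:**
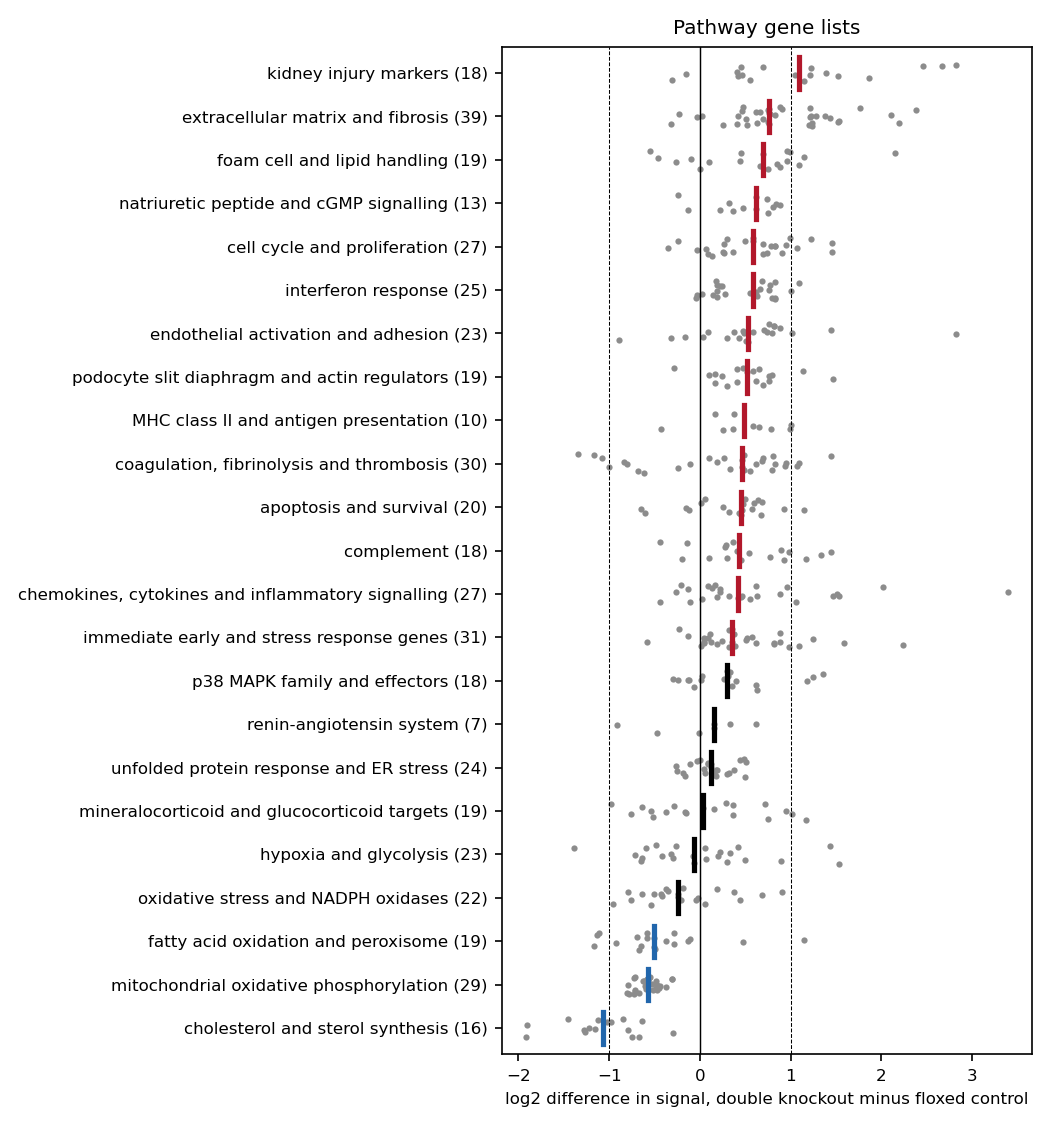
Each grey point is a measured member of a pathway list, placed by its log2 difference in signal (double knockout minus floxed control, horizontal axis), with the list and its number of genes on the vertical axis. Thick bars are list medians (red above and blue below the random lists, black neither) and run from -1.07 for sterol synthesis to 1.10 for kidney injury, and 8 of the 14 red medians lie below the glomerular marker median of 0.57 and so turn negative if recentred on those markers.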

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

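Recentring on glomerular markers was chosen after the data were seen. The other settings were fixed before. No paired analysis was possible because each genotype had 1 array. Under the other 4 scalings every list that stood apart still did so, and the median over all genes moved by less than 0.1 on the log2 scale, most at 75th percentile centring (-0.09). Median and 75th percentile centring multiply each array by a constant, which moves a list and its random lists alike. Apart from effects of the floor, only quantile normalization and removal of the loess trend could therefore have changed a call. The counts moved with the size rule, to 1820 higher and 1331 lower at 1.5-fold and 73 and 34 at 3-fold (68.2% higher). Higher genes numbered 274 with the 60th percentile floor (304 lower) and 302 with the mean over probe sets (286 lower). The share of higher genes was 45.0% with the probe set of median difference, where Des read -0.030 and Egr3 -0.70 because another probe set was used. Recentring, which subtracts the same amount from every gene, gave 77 higher and 2047 lower genes and put Npr1 at -1.27 and Mapk14 at -0.58. It turned 10 higher lists negative by construction, since their medians lay below the subtracted 0.57: podocyte (-0.10), slit diaphragm (-0.041), parietal (-0.041), coagulation (-0.11), endothelial activation (-0.034), chemokines (-0.14), complement (-0.13), MHC class II (-0.080), immediate early (-0.21) and apoptosis (-0.11). The mean in place of the median brought in the p38 list (0.34, against 0.12 with the mean over probe sets) and lost the neutrophil (-0.13) and coagulation (0.18) lists. The neutrophil list was also lost with unmatched random lists (-0.23), without a floor (-0.22) and without probe sets shared between transcripts (-0.22), and the cell cycle list with the 60th percentile floor (0.28). The oxidative stress list came in with unmatched random lists (-0.24) and with the mean over probe sets (-0.28). Apart from the probe set effects, the causes were not tested. Of 94 named genes past 2-fold, 54 stayed past it in every setting fixed before, and 2 changed sign. Npr1 ranged from -0.82 to -0.57 and Mapk14 from -0.11 to 0.02 over those settings. The robust SD of log2 differences was 0.49 in the dimmest 3323 genes, whose median signal was 84.6 against a floor of 52.7, and 0.48 in the brightest 3323. Of the dimmest 173 were at least 2-fold higher and 64 lower, and of the brightest 54 and 155.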

Other observations

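Chosen only after the results were seen were recentring on glomerular markers, the grouping of genes by symbol stem, the tests of RNA integrity, of tubule carry-over for the tubule lists, of the members above a bound, of handling, and of scaling for the sterol genes; the other tests were written before their results.

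Grouping measured genes by the letters that open their symbols gave 158 families of at least 10 genes. Of these, 18 had medians above and 24 below their matched random lists. By chance 7.90 would fall outside if genes within a family varied independently, which related genes need not do. Carbonic anhydrases (Car) had a median log2 difference of -0.70, with 4 of 13 at least 2-fold lower, and aldehyde dehydrogenases (Aldh) -0.65, with 6 of 18. Cytochromes P450 (Cyp) had a median of -0.50, with 10 of 43 at least 2-fold lower and 2 higher, and the aldo-keto reductases (Akr) -0.47, with 3 of 11 lower. Among 281 solute carriers (Slc) the median was -0.30, with 38 at least 2-fold lower and 1 higher. Mitochondrial ribosomal proteins had medians of -0.39 (Mrpl, 47 genes) and -0.43 (Mrps, 29 genes), with none of the first and 1 of the second at least 2-fold lower. These directions held under every scaling tried, in arrays in which the proximal and distal tubule lists, which hold some of the same Slc and Cyp genes, had medians of -0.79 and -0.67.

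The families with the highest medians were C-type lectins (Clec, 0.83, with 4 of 16 at least 2-fold higher and 1 lower) and matrix metalloproteinases (Mmp, 0.81, with 5 of 12 higher and 1 lower). The clustered β-protocadherins (Pcdhb) had a median of 0.73 with 2 of 11 at least 2-fold higher, the tumour necrosis factor receptors (Tnfrsf) 0.69 with 2 of 13, cadherins (Cdh) 0.67 with 3 of 10, and collagens (Col) 0.66 with 5 of 27. All 6 kept their direction under every scaling, including recentring on glomerular markers, where the medians were 0.26, 0.25, 0.16, 0.12, 0.10 and 0.10. The zinc finger genes (Zfp, 294 genes) had a median of 0.22, which became -0.34 after recentring.

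The first pattern weighed is the lower tubule lists beside the higher glomerular lists. The tables argue against unequal RNA integrity, since the 3′ over 5′ ratios of Actb and Gapdh differed by at most 0.067 on the log2 scale, and against a signal-dependent scaling as the whole cause, since the proximal tubule median was -0.62 after the loess trend was removed. Less tubule carried through the sieving into the double knockout sample may account for the lower tubule lists. The proximal and distal medians differed by -0.12 (95% bootstrap interval over genes -0.31 to 0.03), which includes the 0 that a shared loss would give. Any other cause acting on all tubule segments would give it too. Single members were uneven, from -1.66 to -0.28 in the proximal list and from -1.58 to -0.08 in the distal list. Alone it would raise all glomerular cell types by the same amount if their markers were expressed in glomeruli only. The endothelial median lay 0.25 above the podocyte median (interval 0.10 to 0.58). Whether the listed markers are free of tubule expression was not checked. That gap therefore cannot decide whether less tubule covers the higher glomerular lists in full. A loss of tubule transcripts in the tubule cells themselves and an effect of the genotype stay open, untested.

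The second pattern is the higher matrix and injury genes, weighed with the chemokine genes, whose list median of 0.42 lay below the glomerular marker median of 0.57. Enrichment of glomeruli alone cannot be told apart for the lists as a whole, since the share of members above a limit depended on the marker list. The limit was the upper end of the normal 95% range of the markers. Of the 80 distinct members, 19 (23.8%, against 1.43% of all measured genes) lay above the endothelial limit, at 1.25. Above the parietal limit, at 2.11, lay 6 (7.5%, against 0.20%), but that list shares Cd44 with the injury genes. Without the 5 genes on both sides, 8 of 75 (10.7%, against 0.32%) lay above the parietal limit, then 1.82. The endothelial, podocyte and mesangial limits were then passed by 24%, 20% and 12% of members, against 1.43%, 0.92% and 0.55% of all measured genes. A handling response during isolation cannot be told apart, since the 31 immediate early and stress response genes had a median of 0.35 (0.21 with the probe set of median difference), below that of the glomerular markers, while 11 of them lay above it, up to 2.24 for Gadd45b. For the members at least 2-fold higher that had a second probe set above the floor, noise of single probe sets is argued against. Of these second probe sets 100% (16 of 16) were higher too, with a median of 1.48. Members without one, among them Ccl2, Fn1, Lcn2, Tnc, Cxcl2 and Cxcl5, were not covered. An effect of the genotype, more macrophages or other infiltrating cells, and differences between individual animals stay open.

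The third pattern is the lower sterol synthesis genes. For the 9 genes with a second probe set above the floor, noise of single probe sets is argued against. Of these second probe sets 100% were lower too, at a median of -0.78. Signal-dependent scaling is argued against by a list median of -1.06 after the loess trend was removed. Less tubule RNA in the double knockout sample cannot be told apart from a change within cells, since the sterol median differed from the proximal tubule median by -0.28 with an interval of -0.50 to 0.0035, which includes 0. That comparison treats the sterol genes as expressed in the tubule only, which was not checked. A loss of tubule would lower genes also expressed in glomeruli by less, so the interval cannot decide the question. With the mean over probe sets, the sterol and proximal tubule medians were both -0.74. Of the 16 genes, 11 lay below the proximal tubule median, and an effect of the genotype on sterol synthesis in any cell type is a hypothesis that these arrays leave open.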
